A study of Arabidopsis thaliana with 3 samples.

How the data were processed

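Small RNAs were sequenced from immature inflorescences of wild-type Arabidopsis thaliana plants of the Col-0 ecotype, in 3 biological replicates that form 1 group. Per the labels' protocols, the plants grew with 16 h of light and 8 h of dark at 21 °C, total RNA was taken with a column kit that keeps small RNA, and libraries were made with a TruSeq small RNA kit. The deposited table of each library holds 2 columns, a distinct sequence and its counts, and the values are whole numbers from 1 up with no normalization. The sequences run from 15 to 42 nt in all 3 tables. Their names state that reads were trimmed and counted. The trimming tool, its settings and any aligner are not given in the sources used here. The submitters' processing notes name TAIR 10 as the genome build.

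The 3 libraries held 6101300, 6994463 and 9873628 reads in 1582756, 1512578 and 1952170 distinct sequences. Sequences seen in a single read made up 75.5%, 76.9% and 77.5% of the distinct sequences of replicates 1, 2 and 3. Of 3959077 distinct sequences over all libraries, 323059 (8.16%) were in all 3, and these carried 75.4%, 79.8% and 80.1% of the reads of replicates 1, 2 and 3. The floor set by a count of 3 reads was 0.543, 0.477 and 0.330 RPM (reads per 1000000 genome-matched reads) in replicates 1, 2 and 3. Reads are PCR products without molecular identifiers, so floors cover counting error only.

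Every sequence was matched over its full length, with no mismatch, to both strands of the nuclear chromosomes, the chloroplast and the mitochondrion of a TAIR 10.1 reference with its RefSeq annotation. The nuclear chromosomes have the names and lengths of the build named by the submitters, and the mitochondrial sequence differs from it. Matching used code written for this work in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. It gave 7128361 match positions. In a check on simulated data, 2000 of 2000 reads taken from the genome were recovered at their place at 15, 21, 24, 33 and 42 nt. Reads with 1 base changed still matched somewhere in 40.7% of cases at 15 nt, 0.7% at 21 nt and 0.5% at 24 nt, so the origin of the shortest reads is weakly defined. A read with several matches was divided evenly over them. RPM values count reads against all genome-matched reads of the library.

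Each match was given 1 class by its midpoint in a fixed order. First came ribosomal RNA (rRNA), transfer RNA (tRNA), small nuclear or nucleolar RNA, miRNA gene and TAS gene. Then came other noncoding RNA, pseudogene or transposon-derived gene, protein-coding sense, protein-coding antisense and intergenic. Organelles were kept apart, and chloroplast rRNA was counted under chloroplast. The annotation has no transposable element features, so transposon genes could be counted only among its 4851 pseudogene records and the class carries both names. It also lacks the nuclear 25S and most 5S rRNA. After the data were seen, a 25S stretch downstream of each of 2 annotated 5.8S genes, an ITS1 stretch and 459 copies of 5S found with blastn 2.17.0 at 90% identity or more over 100 nt or more were added to the rRNA class. Annotation classes used reads of 18 to 28 nt, and size and locus counts used reads of 20 to 24 nt unless stated.

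The comparisons, their tests, the lists of 69 miRNAs and of TAS and other loci and the rule for naming genes were chosen before the data were examined. The miRNA lists were phase timing, organ patterning, silencing feedback, triggers of secondary siRNAs, nutrient, lineage-specific and pollen. The locus lists were TAS, PPR genes that make phased siRNAs, auxin receptors, silencing genes and targets of RNA-directed DNA methylation. Named were all listed miRNAs with a mean of at least 100 RPM, the 10 annotated MIR genes with the most reads, all TAS and listed loci with at least 10 RPM, and the 10 protein-coding genes with the highest mean RPM of uniquely matched 20 to 24 nt reads. Other named items were chosen after their values were seen. All 69 listed sequences matched their annotated gene or family exactly. TAS4 is not analysed here.

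Values are means over the 3 libraries with the standard deviation (SD). Ratios within a library were tested over libraries with a two-sided exact sign-flip permutation test. Guide and star arms were compared by log2 ratio with a pseudocount of 0.5 reads, at loci with at least 10 reads of both arms together, where star reads started within 2 nt of the expected end. A miRNA's 5' end precision is the share of sense reads over the guide that start at its listed first base. Phasing was read in 21 registers, with antisense reads shifted by 2 nt, at loci with at least 100 reads of 21 nt. The register was chosen in replicate 1 and read in replicates 2 and 3. In a check on simulated loci with 0%, 50% and 90% phased reads, expected register shares of 4.76%, 52.4% and 90.5% were found as 4.69%, 52.8% and 90.8%. Gene-poor windows were the 20% of 500-kb windows with the least protein-coding sequence. Bins of 500 bp were used where each library had at least 5 RPM, and a bin was assigned to a length that held at least 50% of its reads.

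The spread of the libraries was estimated as the common biological coefficient of variation of edgeR 4.0.16 in R 4.3.3, with TMM normalization, an intercept-only design and features with a mean of at least 10 reads. In the check of that estimate on simulated counts, values of 0.2 and 0.4 were found as 0.198 and 0.413 over miRNAs and as 0.199 and 0.398 over bins. Alternatives tried were leaving out each replicate, all reads, distinct sequences, single-match reads, removal of structural RNA and organelles, 1 mismatch (bwa 0.7.19), other length ranges, other denominators, DESeq2 1.42.0 size factors, no low-count filter, another register, and other window and bin settings. Removal of miR165 and miR166 reads, the register of the predicted miRNA cleavage site, the denominator outside structural RNA, reads counted whole at every match for the arms, and windows compared by median or without structural RNA were added after the data were seen. Plots were made with matplotlib 3.10.9. No group comparison was made, since the labels give 1 genotype, 1 organ and 1 growth condition.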

Results

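The study measured the small RNAs of immature flower clusters of wild-type Arabidopsis by sequencing 3 libraries, 1 per biological replicate. The design text and labels state no aim beyond this profile, so each comparison is between kinds of small RNA inside the same library. Of the reads of replicates 1, 2 and 3, 5520082, 6295141 and 9086570 matched the genome exactly, which is 90.5%, 90.002% and 92.0% and a mean of 90.8% ± 1.06 (SD, n = 3). An exact two-sided sign-flip test over 3 libraries cannot go below p = 0.25, the floor of that test and not of the design, so ratios are given with their SD and their direction in each library in place of a call.

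The size comparison asked which Dicer product classes the flower clusters held. The 24-nt class, made by DCL3 for RNA-directed DNA methylation, was the most abundant length with 25.3% ± 6.56 of genome-matched reads (SD, n = 3), at 32.9%, 21.8% and 21.3% in replicates 1, 2 and 3. The 21-nt class, which holds most miRNAs and trans-acting siRNAs, followed with a mean of 13.4% ± 4.01. In replicate 2 it held 10.7% and stood below the 16-nt reads, at 12.6%. Reads of 24 nt exceeded those of 21 nt in all 3 libraries, by a log2 ratio of 0.93 ± 0.09 (exact sign-flip p = 0.25, n = 3). Reads of 23 nt made up 6.83% ± 0.80 and reads of 22 nt 5.03% ± 0.43. Once rRNA, tRNA, other structural RNA and organelle reads were removed, the 24-nt class held 49.0% ± 0.95 and the 21-nt class 23.3% ± 2.56 of the rest. The 21-nt class rested on the miR165 and miR166 family, without which it fell to 5.89% ± 0.54 and the log2 ratio of 24 nt to 21 nt became 2.20. Among distinct sequences the 24-nt class was larger still, at 41.9% against 6.36% for 21 nt. Replicate 2 also had peaks at 16 nt and 33 nt, so the means of 6.98% ± 4.92 and 2.75% ± 2.001 at these lengths became 4.15% and 1.61% without it.

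**Figure D1:**
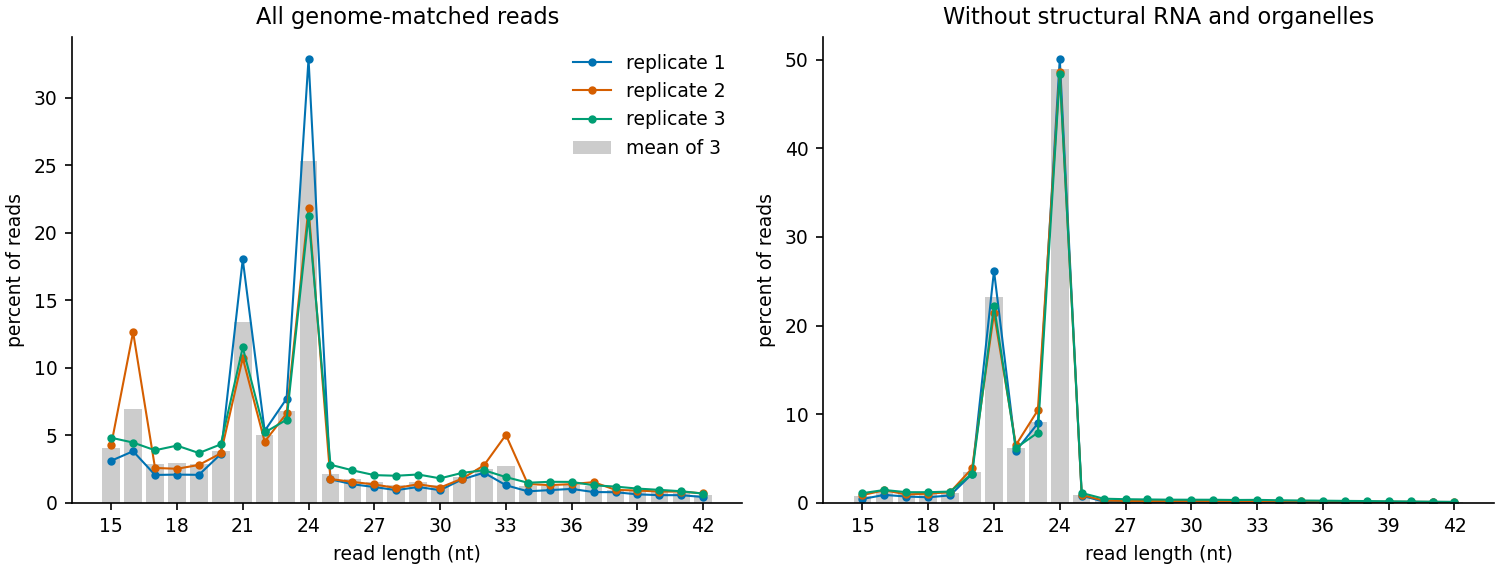
Read length in nt against the percent of reads, for all genome-matched reads and for reads outside structural RNA and organelles, with lines for each replicate and grey bars for their mean. The 24-nt class averaged 25.3% of all and 49.0% of the remaining reads. Replicate 2 stands above both other replicates at 16 and 33 nt in the left panel only.

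The 5' base comparison concerned the feature by which Argonaute proteins sort small RNAs. Reads of 21 nt began with U, the base favoured by AGO1, in 73.7% ± 7.66 of cases (SD, n = 3). Reads of 24 nt began with A, the base favoured by AGO4 and its relatives, in 58.2% ± 1.38 of cases, with U at 15.7%, G at 13.1% and C at 12.97%. Reads of 22 nt were mixed, with U at 35.5% ± 1.02 and A at 28.4%. Reads of 20 nt began with U in 40.3% ± 10.4 of cases. The U of 21-nt reads came from few abundant sequences. It fell to 38.2% ± 6.15 without the miR165 and miR166 family, and among distinct 21-nt sequences U stood at 28.5% against 33.6% for A. The A of 24-nt sequences held at 51.3% among distinct sequences.

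**Figure D2:**
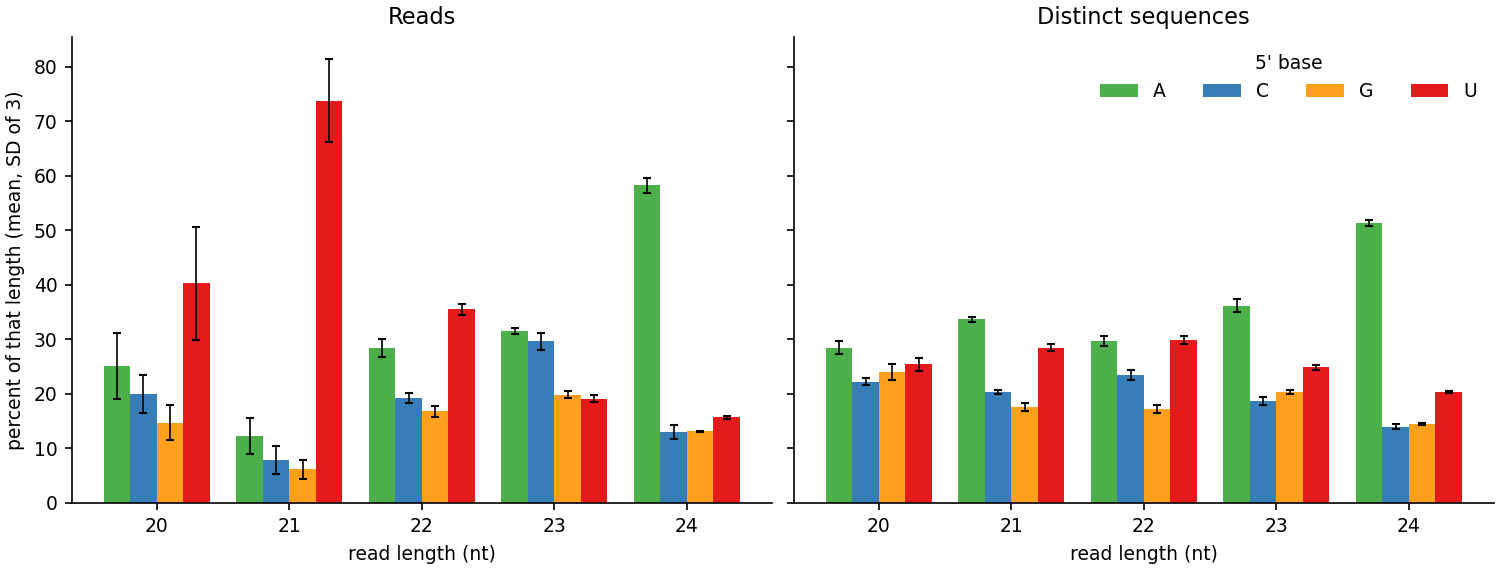
Percent of reads and of distinct sequences that begin with each base at 20 to 24 nt, as bars of the mean with error bars of 1 SD over 3 libraries. U leads among 21-nt reads at 73.7% but not among distinct 21-nt sequences, while A leads at 24 nt in both panels.

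The annotation comparison asked from where in the genome reads of 18 to 28 nt arose. Intergenic regions gave 34.0% ± 5.68 (SD, n = 3), rRNA 20.1% ± 10.02, miRNA genes 15.8% ± 4.55 and the chloroplast 8.36% ± 2.14. Pseudogenes and transposon-derived genes gave 6.53% ± 1.46, protein-coding genes 5.54% ± 0.48 in sense and 3.37% ± 0.51 in antisense, and tRNA genes 1.37% ± 0.71. TAS genes, the noncoding precursors of trans-acting siRNAs, gave 0.78% ± 0.20. The rRNA share was 11.4%, 17.9% and 31.1% in replicates 1, 2 and 3, which moves the share of every other class. Within the 21-nt class, miRNA genes held 67.0% ± 9.06 although they cover 0.0478% of nuclear bases, and TAS genes held 2.87% ± 0.68. Within the 24-nt class, intergenic regions held 63.2% ± 2.90 against 35.8% of nuclear bases, and pseudogenes and transposon-derived genes 12.1% ± 1.11 against 8.74%. Protein-coding genes held 7.04% of 24-nt reads in sense and 5.91% in antisense, against 26.9% and 26.2% of nuclear bases. Transposable elements outside annotated genes count as intergenic here. With single-match reads only, the intergenic share was 55.7%, the miRNA gene share 7.68% and the rRNA share 1.54%, since repeated rRNA and miRNA paralogs drop out.

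The miRNA comparison ranked the listed mature sequences by abundance. The flower clusters were dominated by miR166a, at 58970 ± 28358 RPM (SD, n = 3), and miR165a, at 19597 ± 9037 RPM, which both restrict the class III HD-ZIP genes that set the upper side of lateral organs. These 2 sequences held 71.6% ± 4.75 of all reads of miRNA genes. Next came miR158a, a miRNA of the crucifer family, at 9646 ± 3246 RPM. The listed miRNAs summed to 97458 ± 42211 RPM, and 16 of 69 had at least 100 RPM. Of these miR166a matched 7 places, of which the listed one is on chromosome 2 at 19176241 to 19176261, while miR165a matched 2 places, including chromosome 1 at 78932 to 78952, and miR158a matched only chromosome 3 at 3366349 to 3366368.

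The organ patterning list, of miRNAs that act on leaf and flower form, summed to 85464 ± 38568 RPM, and 9 of its 23 members reached 100 RPM. Beside miR166a and miR165a these were miR159a at 1730 ± 344 and miR159b at 844 ± 244 RPM, which repress GAMYB-like factors, and miR319a at 1595 ± 504 RPM, which represses TCP factors. They also held miR396b, a repressor of growth-regulating factors, at 1611 ± 721 RPM, and miR390a, which primes TAS3, at 645 ± 160.6 RPM. The remaining members were miR167a, a repressor of auxin response factors, at 107 ± 11.3 RPM, and miR394a, which acts on an F-box gene of the shoot meristem, at 105 ± 37.5 RPM. The silencing feedback list summed to 1287 ± 384 RPM, with miR403, which acts on AGO2, at 662 ± 199 RPM, miR168a, which acts on AGO1, at 332 ± 79.0 RPM, and miR162a, which acts on DCL1, at 292 ± 113 RPM. Its other member, miR838, had 0.61 RPM.

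Of 7 listed triggers of secondary siRNAs, miR161.1, which acts on PPR transcripts, was the most abundant at 229 ± 65.0 RPM, followed by miR161.2 at 41.7 RPM. These values count only reads identical to the listed sequence. Of the sense reads over each guide, 42.1% began at the listed first base for miR161.1 and 42.2% for miR161.2. The gap in RPM between these overlapping products may therefore depend on the exact count, and does not rank their first bases. In the same list miR173, the trigger of TAS1 and TAS2, had 8.70 RPM, miR472, which acts on disease resistance genes, 18.9 RPM, and miR393a, which acts on auxin receptors, 7.93 RPM. In the phase timing list miR156a, a repressor of SPL factors that keeps the juvenile phase, had 196 ± 115 RPM, a mean that falls to 129 RPM without replicate 1. Its partner miR172a, which acts on APETALA2-like factors, had 17.8 RPM, and miR157a had 85.2 RPM. The lineage-specific list summed to 9953 ± 3315 RPM, of which miR158a made up most and miR163, a 24-nt miRNA that acts on methyltransferase genes, added 179 ± 53.3 RPM. No member of the nutrient list reached 100 RPM. Its highest was miR399b, a phosphate starvation miRNA, at 89.5 RPM, and 5 of its 11 members were under 1 RPM. The pollen list held miR845a at 10.5 RPM and miR845b at 6.06 RPM, which match primer binding sites of retrotransposons. Spread between libraries was a biological coefficient of variation of 0.232 over 52 miRNAs, and replicate 2 decided much of it, since the value was 0.147 without that library. Shares of reads limit all these values, because rRNA and tRNA fragments differed between libraries.

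**Figure D3:**
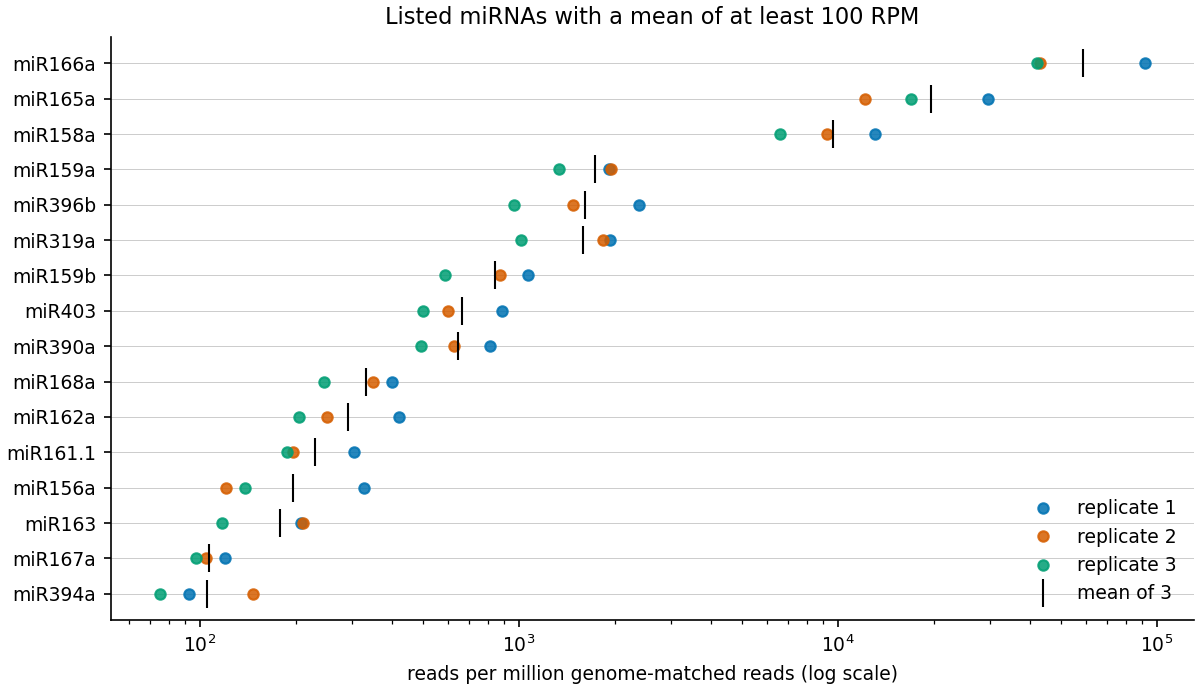
Abundance in RPM on a log axis of the 16 listed miRNAs with a mean of at least 100 RPM, with a point for each replicate and a tick for the mean. The values range from 105 RPM for miR394a to 58970 RPM for miR166a.

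Of 326 annotated MIR genes, 89 had at least 10 RPM, and 21 nt was the main read length at 65 of them, 20 nt at 11, 24 nt at 6 and 22 nt at 4. The 10 MIR genes with the most reads were MIR166a to MIR166g, MIR165a, MIR165b and MIR158a. MIR166a, on chromosome 2 at 19176108 to 19176277, had 11496 ± 5413 RPM (SD, n = 3). MIR158a had 10911 ± 3670 RPM, MIR165a 10262 ± 4656 RPM and MIR165b 9902 ± 4546 RPM, while MIR166e was the lowest of the 10 at 8498 ± 4071 RPM. Paralogs share the guide sequence and its reads were divided over them, so values of single MIR165 and MIR166 genes are not separate measurements.

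The arm comparison asked which strand of each miRNA duplex was kept. At 30 loci with enough reads, the listed guide exceeded the opposite arm in all 3 libraries at 21 loci, and was at least 10-fold higher at 13. The log2 ratio of guide to opposite arm was 11.95 ± 1.34 for miR159b, 8.80 ± 0.88 for miR165a, 8.76 ± 0.35 for miR396b, 8.63 ± 0.36 for miR158a and 8.01 ± 0.30 for miR403 (SD, n = 3). The opposite arm was taken as the other annotated mature product of the gene, and it exceeded the listed one in all 3 libraries at 9 loci. These were miR447a at -4.33 ± 0.58, miR780 at -3.99 ± 0.24, miR172e at -3.30 ± 0.44, miR824 at -2.57 ± 0.14, miR170 at -2.28 ± 0.58, miR171b at -1.86 ± 0.23, miR167a at -1.43 ± 0.52, miR171a at -0.53 ± 0.56 and miR169a at -0.50 ± 0.31. At the miR780 gene the other product reached 693 RPM against 44.1 RPM for reads of the listed arm, and at the miR167a gene 173 RPM against 63.1 RPM. The miR780 products abut on the same strand, at 8504145 to 8504165 and 8504166 to 8504186, so they are not the strands of a duplex. The miR447a products lie close too, at 1528148 to 1528168 and 1528190 to 1528211, and were not shown to be opposite arms. Neither ratio is therefore read as a choice of strand. The median over loci was 2.95 ± 0.09, and each single ratio has an exact sign-flip p of 0.25 at the lowest. Of these 9 calls, 3 changed when shared reads were not divided over paralogs. With each read counted whole at every match, the other product stayed higher in all 3 libraries at 6 loci. These 6 include miR780 and miR447a, whose ratios are not read as a choice of strand. Both also count among the 30 loci and in the median. The 3 that changed, miR167a, miR171a and miR169a, at -0.34 ± 0.55, 0.41 ± 0.55 and -0.01 ± 0.26, lay on both sides of 0. At miR170 and miR172e the listed guide has 1 genome match, and whole counting lowered the ratios to -3.27 ± 0.58 and -4.27 ± 0.42. Their opposite-arm reads thus match other places too. Whole counting could only strengthen these calls, and the reads cannot be assigned to the locus. The miR172e guide also had as few as 3 reads in a library. For the miR159b ratio, replicate 2 had 0 reads of the opposite arm, so its size rests on the pseudocount.

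Cleavage at the 5' end was precise for most of these miRNAs. The median share of reads that began at the listed base was 96.3% ± 0.12 over the 16 miRNAs of at least 100 RPM (SD, n = 3). It was highest for miR396b at 99.95% and lowest for miR161.1 at 42.1% ± 6.55, whose gene makes the overlapping miR161.2. For miR166a and miR319a the shares were 74.6% and 75.3%. Each read was divided by its genome matches, 7 for the exact miR166a and 2 for miR319a. Variants with fewer matches can therefore weigh more, so these 2 shares depend on that division. With single-match reads only the median was 72.1%, since reads of family members with several copies then drop out.

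The trans-acting siRNA comparison concerned loci that make secondary siRNAs after miRNA cleavage. TAS1C, on chromosome 2 at 16537288 to 16538277, gave the most 20 to 24 nt reads at 2276 ± 744 RPM (SD, n = 3). TAS2, beside it at 16539384 to 16540417, gave 1480 ± 482 RPM, and TAS3A, the source of siRNAs against auxin response factors, gave 843 ± 219 RPM from chromosome 3 at 5861491 to 5862437. TAS1B gave 226 ± 64.4 RPM, TAS3B 171 ± 34.5 RPM, TAS1A 159 ± 47.9 RPM and TAS3C 12.5 ± 1.44 RPM. Reads of 21 nt made up 68.0% at TAS1C, 77.1% at TAS2 and 78.4% at TAS3A. All 7 listed PPR genes, which encode pentatricopeptide repeat proteins and are targets of TAS siRNAs and miR161, gave at least 10 RPM. AT1G62910 had 73.1 ± 21.1 RPM, AT1G63150 68.5 ± 19.3 RPM, AT1G63080 63.5 ± 21.4 RPM, AT1G63130 58.8 ± 19.2 RPM, AT1G62930 45.1 ± 14.03 RPM, AT1G63400 30.03 ± 9.81 RPM and AT1G62590 10.5 ± 3.05 RPM.

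Counted by reads, the share in register was highest at TAS1C. There 79.5% ± 4.04 of 21-nt reads stood in the register chosen in replicate 1 (SD, n = 2), against 4.76% for even use of the registers. The share was 52.2% ± 0.32 at TAS2, 52.1% ± 1.10 at TAS1B, 50.4% ± 0.89 at TAS1A, 36.2% ± 0.85 at TAS3A and 25.1% ± 2.08 at TAS3B, with a mean of 49.2% ± 0.19 over these 6 loci. Among the PPR genes it ran from 13.2% at AT1G63400 to 54.9% at AT1G63150, with 51.8% at AT1G62910. By distinct sequences the PPR shares ran from 6.59% at AT1G62930 to 13.8% at AT1G63150, and no register was predicted for these genes. The register of TAS1A, TAS1B and TAS1C was that of the predicted miR173 cleavage site, while the main register of TAS2 lay at an offset of -2 nt from it and the predicted register held 27.2%. The main registers of TAS3A and TAS3B did not match their predicted miR390a sites, with offsets of 8 and -5 nt and 10.5% and 2.37% of reads in the predicted register. These sites were weak predictions, with mismatch scores of 5 and 6.5 under a limit of 7, against 1.5 to 2.5 for the miR173 sites. The disagreement is therefore not a firm property of the loci. Among distinct sequences of the TAS loci the mean share was 11.6%, so a few abundant siRNAs carried most of the phasing signal. By that count TAS1C, at 9.33%, stood below TAS1B at 15.9%, TAS1A at 13.4%, TAS2 at 13.1% and TAS3A at 9.51%. Only TAS3B, at 8.55%, was lower, so the order by reads was not kept. An abundant siRNA in any register would also exceed 4.76%, so a share above that value does not by itself show phasing.

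**Figure D4:**
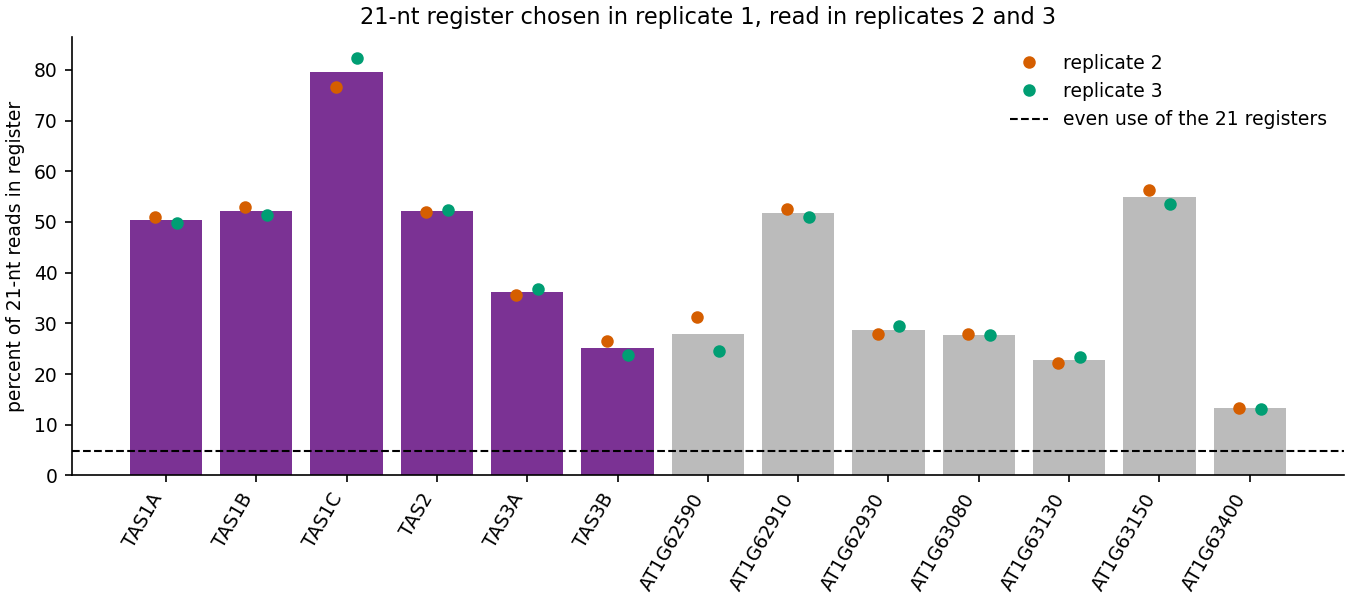
Percent of 21-nt reads in the register chosen in replicate 1 at 6 TAS loci (purple) and 7 PPR genes (grey), with points for replicates 2 and 3, bars for their mean and a dashed line at 4.76% for even use of 21 registers. TAS1C is the highest at 79.5% and AT1G63400 the lowest at 13.2%.

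Other listed loci gave few reads. The auxin receptor genes AFB3, AFB2, TIR1 and AFB1 had 9.87, 5.11, 1.79 and 0.65 RPM. Among silencing genes AGO1 had 9.19 RPM and DCL1 5.39 RPM, and among targets of RNA-directed DNA methylation ROS1 had 7.95, SDC 6.45 and FWA 5.07 RPM. AGO2, an Argonaute of antiviral defence, had 25.6 ± 7.10 RPM (SD, n = 3). Of this, 93.9% ± 0.64 was a 20-nt form of miR403, TTAGATTCACGCACAAACTC, which also matches the antisense strand of AGO2 on chromosome 1 at 11185224 to 11185243, and 1.52 ± 0.26 RPM remained without it.

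Among protein-coding genes, the 10 with the most uniquely matched 20 to 24 nt reads were led by AT4G08545, annotated as a receptor-like protein, at 2271 ± 440 RPM (SD, n = 3) from chromosome 4 at 5436600 to 5439167. AT1G49260, annotated as like a mechanosensitive ion channel, had 1409 ± 110.0 RPM from chromosome 1 at 18225870 to 18226967, and AT5G22860, annotated as a serine carboxypeptidase, 838 ± 121 RPM. The protein kinase genes AT4G29654, AT2G18530 and AT2G16620 had 798 ± 122, 540 ± 98.5 and 490.1 ± 84.1 RPM. AT3G21170, an F-box gene, had 694 ± 102 RPM, and the uncharacterized genes AT2G02440 and AT5G56070 had 668 ± 88.5 and 635 ± 57.0 RPM. In these 9 genes 66.4% to 84.3% of the reads were 24 nt. AT5G10946, at 536 ± 351 RPM, was 97.2% 21 nt and overlaps the MIR156d gene, and its mean was 333 RPM without replicate 1.

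The chromosome comparison asked whether siRNA classes differ between gene-poor and gene-rich regions. In 48 gene-poor 500-kb windows, 24-nt reads stood at 4.01 ± 1.18 RPM per kb against 1.59 ± 0.39 in 192 other windows (SD, n = 3). The log2 ratio was 1.32 ± 0.06 and was positive in all 3 libraries (exact sign-flip p = 0.25). The mean of 21-nt reads was lower, with 0.63 ± 0.07 RPM per kb in gene-poor and 1.19 ± 0.42 in other windows and a log2 ratio of -0.85 ± 0.50. The direction of the 21-nt ratio rested on few windows, since the median window had 0.23 ± 0.05 RPM per kb in gene-poor and 0.12 ± 0.01 in other regions, a log2 ratio of 0.94 ± 0.20. The gene-poor window of chromosome 3 at 14000001 to 14500000 held 50.6% ± 14.8 of the gene-poor sum, and 90.8% ± 1.32 of its 21-nt reads were rRNA. Without structural RNA the ratio of means was -1.88, and with single-match reads only, which leave out most rRNA, MIR165 and MIR166 reads, it was 0.13. The 24-nt ratio stayed positive under the same settings, at 1.47, 1.28 and 1.08. In the tenth of windows with the least coding sequence the 24-nt ratio was lower, at 0.74, and still positive.

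**Figure D5:**
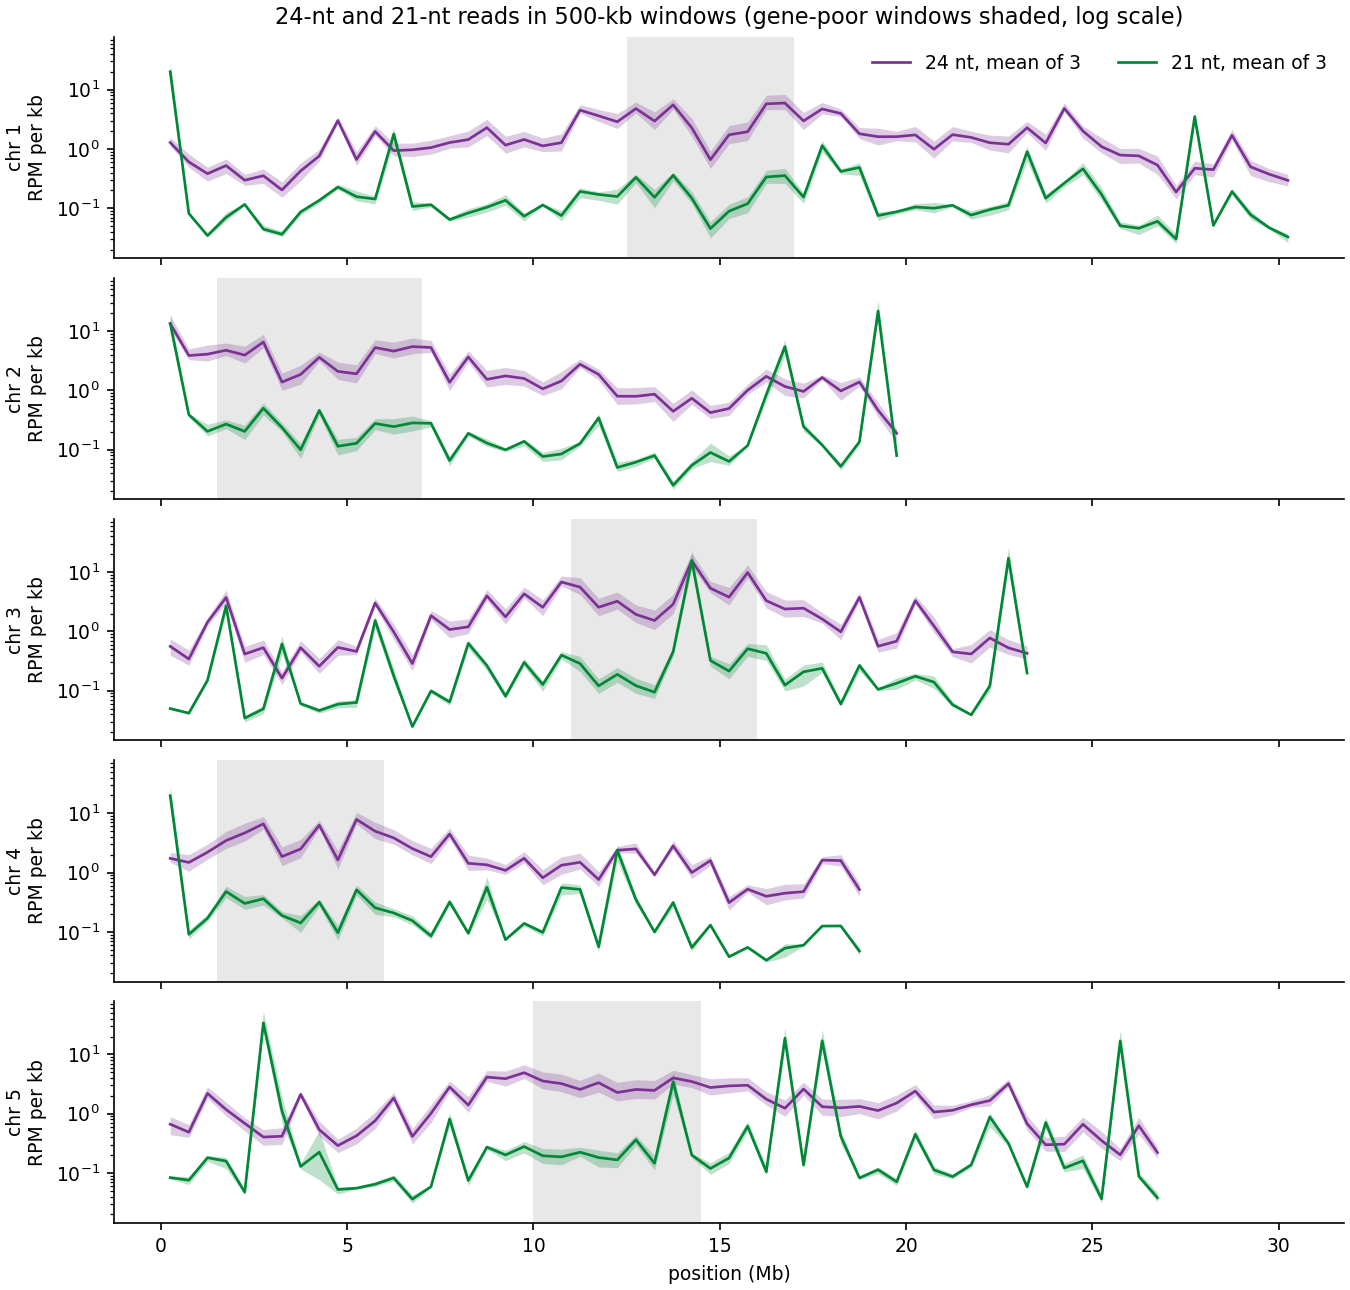
Density of 24-nt (purple) and 21-nt (green) reads in RPM per kb on a log axis along the 5 chromosomes in 500-kb windows, as the mean of 3 libraries with a band from lowest to highest and gene-poor windows shaded. The 24-nt class averaged 4.01 RPM per kb in shaded and 1.59 in other windows, and the 21-nt class forms narrow peaks.

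Most regions rich in small RNA were of the 24-nt kind. Of 7348 bins of 500 bp with at least 5 RPM in every library, 6797 (92.5%) were mainly 24 nt and 124 (1.69%) mainly 21 nt. Bins classed as intergenic made up 76.7% of the 24-nt bins and those of pseudogenes or transposon-derived genes 10.5%. Of the 21-nt bins, 60 were classed as intergenic, 10 as TAS genes, 10 as miRNA genes and 9 as other noncoding RNA. A MIR gene shorter than its bin can fall in a bin classed as intergenic, so the 60 may include MIR genes. Protein-coding genes held 29 bins of the antisense and 2 of the sense class. A bin has no strand and took the class with the most bases over both strands, so this split does not give the strand of the reads. Intergenic bases counted on both strands, while bases of protein-coding genes were divided between sense and antisense. The rule therefore favours the intergenic class over protein-coding genes. The 24-nt bins held 44.6% ± 2.68 and the 21-nt bins 19.5% ± 3.62 of nuclear 20 to 24 nt reads (SD, n = 3). A minimum of 1 RPM gave 23420 and a share of at least 80% gave 1633 of the 24-nt bins, so their number rests on these limits.

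The spread between the 3 libraries was measured over sequences and bins. The chi-square per degree of freedom between pairs was 21.0 to 37.8 over all sequences and 3.34 to 3.94 over nuclear sequences of 20 to 24 nt, where 1 is counting error alone. Separate plants counted in PCR reads exceed that value in any case, so it describes the spread and tests nothing. Pearson's r across 33550 bins, which are not independent replicates, was 0.949 to 0.954. The biological coefficient of variation over 16458 bins was 0.220.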

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

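The tests of miR158a in this part were chosen only after the result was seen, except the test of its U addition against the highest other miRNA. With 3 libraries in 1 group, replicates were not tested for lying apart from the others, and no biological explanation was tested, because the labels give no difference between replicates. The results here are signals in reads that the comparisons left out, above the 3 reads that a count of 0 allows.

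Reads that match tRNA-His only after a G is set before its mature 5' end numbered 138079, of which 14166, 115254 and 8659 were in replicates 1, 2 and 3. They made up 94.1% ± 4.67 (SD, n = 3) of reads at that end of tRNA-His, a tRNA to which an enzyme adds this G after transcription. Other tRNA 5' ends had 5, 4 and 3 reads with an added G over 615 genes. Reads of a tRNA 3' end followed by CCA, the tail that carries the amino acid, numbered 138756, against 87, 120 and 334 reads ending in CCG in replicates 1, 2 and 3.

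Unmatched reads of miR158a with 1 to 3 added U at the 3' end numbered 25307, which is 11.2% ± 1.58 of its reads (SD, n = 3). Of these, 23962 had a single added U, which is also the first base of the adaptor. An adaptor base left after trimming at a rate that does not depend on the insert is argued against, since the share with a single U was at least 63.2 times that of miR159a in each library. A rate of U addition shared by all miRNAs in library preparation is also argued against by 9 listed miRNAs with no U next in the genome. Their shares ranged from 0.283% for miR159a to 41.3% ± 1.73 for miR319a. In each library miR158a had at least 34.6 times the lowest share, a test chosen after the result was seen. The test chosen before would have counted against a shared rate only had miR158a stood above the highest other miRNA. It was at the lowest 0.244 times that miRNA, so this earlier test did not decide. A tailing enzyme that prefers some miRNAs may be the source and stays a hypothesis, beside a bias of the ligation for some ends, which was not tested.

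Reads that hold the start of the 3' adaptor numbered 17 over the 3 libraries. Reads that hold the end of the 5' adaptor numbered 3669, and reads that hold the stop oligonucleotide of the kit numbered 12974.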

How the results depend on the processing

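Of 144 alternative values that kept all libraries, 40 moved by less than the spread between replicates, or by less than 1.5 times for counts, 102 moved further and 2 changed sign. Leaving out a library cannot move a mean by more than the spread, so means were read by fold. Of 114 not on a log2 scale, 1 moved by over 1.5 times, that of miR156a without replicate 1, at 129 RPM. The 114 leave out the 16-nt and 33-nt shares, which moved by 1.68 and 1.71 times without replicate 2. They also leave out AT5G10946, which moved by 1.61 times without replicate 1. Of 12 bin counts and coefficients of variation with a library left out, 11 stayed within 1.5 times, the exception being the miRNA coefficient of variation, which ranged from 0.147 to 0.297. The values without miR165 and miR166, with the predicted register, scaled by reads outside structural RNA, with reads counted whole, and for windows by median or without structural RNA were chosen only after the data were seen. The genome-matched share was 94.2% for sequences with at least 2 reads and 97.5% with 1 mismatch. With distinct sequences, the 21-nt share was 6.36%, the 24-nt share 41.9%, their log2 ratio 2.71, U at 21 nt 28.5%, U at 22 nt 29.8%, A at 24 nt 51.3%, the intergenic share 53.3%, pseudogene or transposon-derived 16.4%, miRNA gene 0.296%, rRNA 3.56% and phasing 11.6%. Without structural RNA and organelles these were 23.3% and 49.0% for 21 and 24 nt, 1.08 for their log2 ratio, and 85.5%, 39.4% and 60.6% for U at 21, U at 22 and A at 24 nt. Without miR165 and miR166, the 21-nt share was 5.89%, the log2 ratio 2.20, U at 21 nt 38.2% and U at 22 nt 33.8%. With all reads, U at 22 nt was 37.3%. With single-match reads, the intergenic share was 55.7%, pseudogene or transposon-derived 8.90%, miRNA gene 7.68%, rRNA 1.54%, 5' precision 72.1%, the median log2 guide ratio 2.61, phasing 47.1%, the 24-nt window ratio 1.08, the 21-nt window ratio 0.13, which changed sign, and 21-nt bins 72. The intergenic share at 20 to 24 nt was 39.9%, and phasing in the predicted register 37.0%. The miRNA sum was 897024 and 198385 when scaled by miRNA gene reads and by reads outside structural RNA, by construction of the denominators. By the median over windows, the 24-nt ratio was 1.47 and the 21-nt ratio 0.94, which changed sign. With reads counted whole, the median log2 guide ratio was 3.21. The 24-nt window ratio was 1.39 with 100-kb windows and 0.74 for the 10% of windows with the least coding sequence, and under these settings the 21-nt ratio was -0.26 ± 0.68 and -0.36 ± 0.74 (SD, n = 3), each with a spread across 0. Bins of 24 and 21 nt numbered 23420 and 220 at 1 RPM, and 1633 and 63 at 80%. Removing reads or counting each sequence once changes what is counted. Beyond that the cause was not tested. Among single classes and miRNAs, 18 of 77 other values stayed within the spread, 51 were higher and 8 lower. Depth limits values below the floors of 0.330 to 0.543 RPM.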

Other observations

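The tests of the tRNA and rRNA patterns in this part were chosen only after the result was seen, except those on size selection at 16 nt and on the share of rRNA reads of at least 25 nt. The items in the next paragraphs were also chosen after their values were seen.

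The 24-nt reads with a single match were concentrated in few places. The 100 bins of 500 bp with the most reads, of 76591 with any, held 23.4% ± 3.01 of them (SD, n = 3), and 88 bins were in the top 100 of all 3 libraries. The 100 bins chosen in 1 library held 23.2% ± 1.48 in the other 2. Of the 100, 77 were classed as intergenic by the same rule, which favours that class, and 28% lay in gene-poor windows. The highest, on chromosome 4 at 4105001 to 4105500, had 1467 ± 142 RPM, with 84.5% of reads on the plus strand, and the next, at the transcribed pseudogene AT3G43832 on chromosome 3, had 1342 ± 220.3 RPM.

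The most abundant 23-nt sequence, CTAACAGACCGGTAGACTTGAAC, came from the chloroplast and not from a nuclear siRNA locus. It is the last 23 nt of the chloroplast 4.5S rRNA, at 107679 to 107701 and 130948 to 130970, and had 9193 ± 398 RPM (SD, n = 3), which is 13.5% ± 1.12 of 23-nt reads. Without it, C at the 5' end of 23-nt reads was 18.6% ± 1.28 in place of 29.6%. Of 8 miRNAs of other plants and animals searched by name, each had 0 reads, which allows up to 3 reads per library.

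Reads of tRNA genes made up 19.1% of the genome-matched reads of replicate 2, against 4.67% and 2.80% in replicates 1 and 3, and 97.5%, 92.4% and 81.8% of them in replicates 2, 1 and 3 began at the mature 5' end. In replicate 2, 51.8% of them were 16 nt and 20.5% were 33 nt long. General breakdown of RNA as the whole source is argued against, since protein-coding sense reads of 26 to 42 nt were 2.18% of reads outside structural RNA in replicate 2, above the 0.972% of replicate 1 but below the 4.03% of replicate 3, which had the lowest tRNA share. A size selection for 16 nt is argued against by the ratio of 16-nt to neighbouring rRNA and chloroplast reads, which was 0.727 of the highest other library, and 1 over-amplified sequence by the share of 13.4% that remained without GGGGATGTAGCTCAGA of tRNA-Ala. A difference in tRNA 5' fragments between the plants of the replicates stays open, since the labels name none and no biological explanation was tested.

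Reads of rRNA made up 43.1% of the genome-matched reads of replicate 3, against 19.6% and 24.3% in replicates 1 and 2. Breakdown of RNA in replicate 3 is consistent with protein-coding sense reads of 26 to 42 nt, at 4.03% of reads outside structural RNA against 0.972% and 2.18%. Longer inserts let through by the size selection are argued against as the whole source only by a test chosen after the result was seen. In it, rRNA made up 8.05% of the 24-nt reads of replicate 3 against 2.43% and 3.99% in replicates 1 and 2. The test chosen before went the other way, with reads of at least 25 nt at 48.4% of rRNA reads in replicate 3 against 47.9% and 47.7%. The nominal excess of 48.4% was what that explanation had called for, but a shift of this size leaves the excess at 24 nt unexplained. The fit with breakdown was found and tested on the same libraries and stays a hypothesis.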
